A study of Drosophila melanogaster with 2 samples.

How the data were processed

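Chromatin immunoprecipitation with sequencing (ChIP-seq) was analysed for l(3)neo38, a Drosophila zinc finger gene, from 2 biological replicates that form 1 group. Per the labels, the flies carried a transgene for an l(3)neo38 protein fused to enhanced green fluorescent protein. Embryos of 0 to 24 h were used, and the chromatin was precipitated with an antibody to GFP. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp. Other factors, other stages and untagged embryos were not analysed here, so no conditions could be compared.

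The deposited files are peak lists on the builds dm6 and dm3. Per the descriptions deposited with the lists, each replicate has its own list of peaks and background entries made from its alignments and a control. A further list came from the alignments of both replicates pooled. The thresholded list, the authors' list after the irreproducible discovery rate (IDR) procedure, was derived from these 3 lists. The peak caller, its version and the IDR threshold are not given in the sources used here. Each replicate list and each pooled list held exactly 30000 entries on either build.

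The signal value of each entry is the peak strength that the authors deposited. It was used only to rank and describe entries within a list, since its normalization is not given in the sources used here. The deposited −log10 q value of each entry was not used for ranking, because all 3953 thresholded peaks on dm6 held the same value of 3.96. The deposited score column held one value throughout, so the stricter threshold tried was the 1976 peaks with the largest signal. The other deposited value used is the summit, the position within each interval that the authors gave. No read counts were in the lists analysed here, so the depth of each replicate is unknown. Intervals on shares cover counting error over peaks or genes only.

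Positions on dm6 were compared with the Ensembl 115 gene annotation, on the 6 arms 2L, 2R, 3L, 3R, 4 and X. The chromosome names and lengths of the release 6 genome sequence were used. No annotation of dm3 was used here, so dm3 lists served for counts, chromosome shares and replicate matching only, and no position was converted between builds. A summit within 500 bp of an annotated transcript start was called a promoter summit. The remaining summits were placed, in order, in 5' UTR, coding exon, 3' UTR, other exon, intron or intergenic sequence. Random positions, 10 per peak on the same chromosome, gave the comparison by two-sided Fisher's exact test.

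Agreement of the replicates was measured by matching summits within 100 bp among the strongest entries of each replicate list, as many as there are thresholded peaks. Random placement of the summits on their chromosomes, 1000 times, gave the chance level. Correlations were computed across peaks, which are not independent replicates, with 100000 permutations.

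A gene was called promoter-bound when a thresholded summit lay within 500 bp of any of its transcript starts. The 34 gene lists, 32 sequence motifs, tests and most alternatives were fixed before the data were examined. Each list was tested against all protein-coding genes, or against all genes for classes of non-coding RNA, by two-sided Fisher's exact test with Benjamini-Hochberg adjustment at 0.05. Of the list names, 11 were matched through older symbols and 5 were not found. Genes are not independent replicates, and these p-values do not measure the spread between embryos.

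Sequence was compared between a window reaching 50 bp to either side of each summit and a window of the same width centred 350 bp away, on a side drawn at random. Motifs and all 8-mers found in at least 1% of windows were tested with the exact McNemar test and Benjamini-Hochberg adjustment, with both strands counted together. GC content was compared by a sign-flip permutation test.

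Genes named in the text followed a rule fixed together with these lists. It takes l(3)neo38, the genes nearest to the 20 strongest peaks away from l(3)neo38, 4 members of each list that passed and up to 2 of each other list, by promoter peak strength, and the 5 genes with the most summits within 2000 bp. The text gives a selection of these in full and summarises the rest.

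Alternatives covered the genome build, a stricter threshold, match distances, promoter windows, backgrounds, controls, and each replicate's own list in place of the thresholded list. Random gene lists matched on the number of transcript start clusters and on gene length, and the omission of l(3)neo38 from the list that holds it, were chosen after seeing the data. The procedures were tested on simulated data. An 8-mer placed in 5% of 3953 random windows ranked 1st of 863 8-mers and was measured at 5.19%. With nothing placed, 0 of 860 8-mers passed. Those windows lay at random places, so the GC difference between real summits and flanks was not simulated. Random bound sets drawn evenly from 13945 genes gave any passing list in 2 of 100 draws. Differences between genes in length and in transcript starts were not simulated either. A segmentation list drawn with 5 times the weight of other genes passed in 74 of 100 draws. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.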

Results

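The ChIP-seq peaks of l(3)neo38-GFP in Drosophila embryos of 0 to 24 h were described from 2 biological replicates of 1 group. Embryos of this age range span the whole of embryogenesis, so each list averages over stages and tissues. The authors' thresholded list held 3953 peaks on dm6, covering 1.46 Mb or 1.09% of the 6 chromosome arms. Their signal values, which are the authors' own, ran from 140.7 to 3625 with a median of 209.6. All 3953 were the strongest entries of the list made from pooled replicates. Summits within 250 bp of each other formed 3641 clusters, so some regions held several summits. The depth of the replicates is unknown. Without untagged embryos or other factors, whether a peak is particular to l(3)neo38-GFP could not be tested, and genes called bound are genes with a peak.

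Several peaks lay at the tagged gene itself. l(3)neo38 (FBgn0265276) lies at 3R 11765038 to 11779128 on the minus strand, and 12 thresholded summits fell within 2000 bp of it, 9 of them inside the gene body. The strongest, with a signal value of 1170, had its summit at 3R 11774022, 452 bp from an l(3)neo38 transcript start. It ranked 22nd of the 3953 peaks, 25th in replicate 1 and 20th in replicate 2. A further promoter summit at 3R 11777295 had a signal value of 624.1. The summits outside the gene body were promoter summits of other genes, Lk6 (32 bp from its start) and lncRNA:CR45595 (285 and 332 bp). Some summits inside it shared an interval, such as 11774022 and 11774223. Those at 11776027 and 11780356 had no match in replicate 2. The sequence within 50 bp of the strongest summit, 3R 11773972 to 11774072, read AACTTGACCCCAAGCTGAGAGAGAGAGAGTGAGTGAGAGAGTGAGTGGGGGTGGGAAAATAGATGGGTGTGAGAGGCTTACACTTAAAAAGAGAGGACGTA. Per the labels the line is transgenic for this gene, and whether it carries extra copies of the locus is not given in the sources used here.

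**Figure D1:**
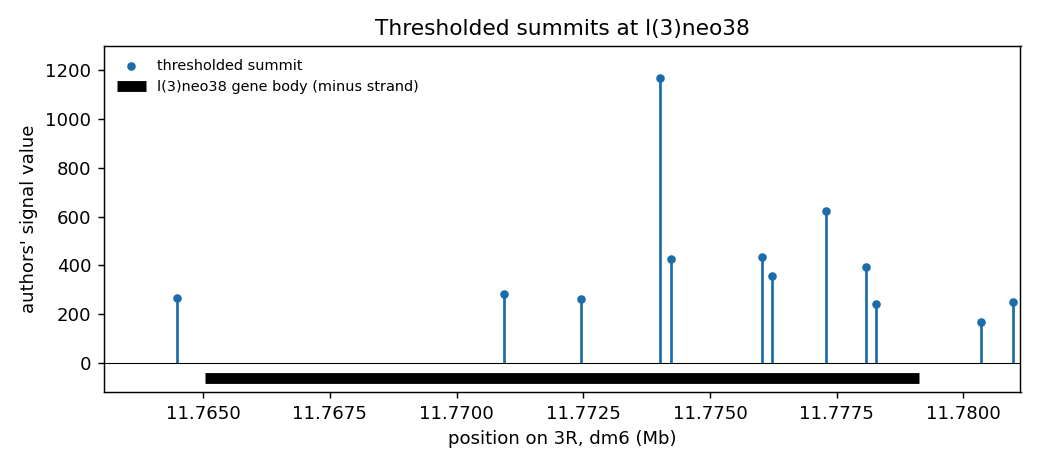
Signal value of each thresholded summit (vertical axis, the authors' unit) against its position on 3R in dm6 (horizontal axis, Mb), within 2000 bp of l(3)neo38. Each stem is 1 of the 12 summits, the black bar is the gene body, and the tallest stem is the summit at 11774022 with a signal value of 1170.

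The 20 strongest peaks elsewhere were assigned to the nearest transcript start. The genes included kay, the fly Fos protein, mirr, an Iroquois homeobox gene, brk, a repressor of Dpp targets, and erm, a zinc finger gene of neural progenitors. Others were osa, a subunit of the Brahma remodelling complex, Trl, which encodes GAGA factor, and ph-p, a Polycomb group gene. The strongest of all, with a signal value of 3625, was intergenic at 2R 22678040 to 22678792, 4821 bp from the start of lncRNA:CR44761. It ranked 1st in both replicates. The next, with a signal value of 1911, lay in an intron of so, the eye determination gene sine oculis, at 2R 7429038 to 7429686. The peak at erm covered 2L 1970374 to 1970963 with a signal value of 1905, and its summit was 282 bp from the start. The peak at kay covered 3R 29772765 to 29773476 with a signal value of 1878, inside the gene and 277 bp from a start. At mirr the peak covered 3L 12692803 to 12693553, in intergenic sequence 504 bp from the start, with a signal value of 1797. At brk it covered X 7306494 to 7307086, 1153 bp from the start and inside an intron of CG1677, with a signal value of 1776. The peak nearest to cbt, at 2L 480764 to 481357, lay in an intron of ush, and the peak nearest to CG45075 lay in an intron of Kr-h1. Of the 20 peaks, 7 were promoter summits, 9 were intronic and 4 were intergenic. Every one of the 20 was matched in both replicates, at rank 26 or better in replicate 1 and rank 55 or better in replicate 2.

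The genes with the most summits in the gene body and 2000 bp around it were sbb with 30, jing with 28, lncRNA:CR44357 with 28, tara with 21 and Eip75B with 17. All are long, from 34.7 kb for tara to 239.3 kb for lncRNA:CR44357, which spans other genes. Per 10 kb, tara held 5.43 summits and Eip75B, an ecdysone-induced nuclear receptor gene, held 1.44.

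How far the replicates shared these peaks was asked next. Of the thresholded peaks, 61.8% (2442 of 3953, 95% exact interval 60.2 to 63.3) lay within 100 bp of a summit among the 3953 strongest entries of each replicate. Random placement gave 0.33% on average and at most 0.658% in 1000 draws. The set of replicate 1 held 81.8% and that of replicate 2 held 77.1%, each counting the peaks in both, and 117 peaks were in neither set. Over the 3595 peaks matched in both full lists, signal correlated across peaks with Spearman's rho of 0.549 and Pearson's r of 0.624 on the log2 scale. The permutation p was 1e-05 for both of the 2 correlations, which is the smallest that 100000 permutations can give. The thresholded list was itself derived from both replicates, so these shares are not independent evidence of agreement. Peaks are not independent replicates.

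Peaks gathered at promoters and were rare in coding exons. Of the 3953 summits, 33.1% (1307, 95% exact interval 31.6 to 34.6) lay at promoters, against 13.8% of random positions (odds ratio 3.08, Fisher's exact adjusted p = 1.22e-182). Coding exons held 0.632% of summits against 13.8% of random positions (odds ratio 0.0399, exact adjusted p = 2.82e-197). Introns held 42.3% of summits, intergenic sequence held 20.5%, and random positions 39.5% and 27.02%. The share in 3' UTR was 0.759% against 4.35%, while 5' UTR, at 1.04% against 0.772%, did not pass (exact adjusted p = 0.0746). The 24568 weaker pooled entries that overlapped no thresholded peak had a promoter share of 15.4% and a coding exon share of 5.81%. Of these weaker entries 46.2% were intronic, more than among the thresholded summits, and 29.2% were intergenic.

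**Figure D2:**
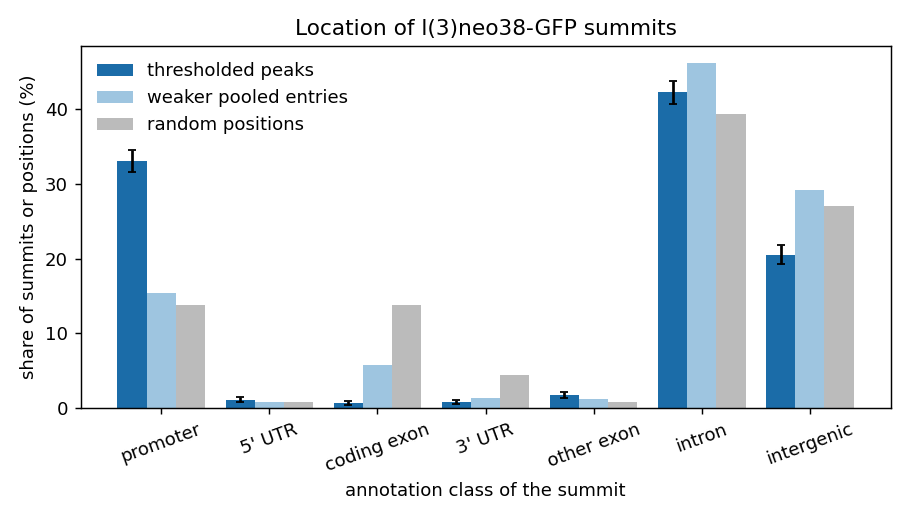
Share of thresholded summits, of weaker pooled entries and of random positions (vertical axis, %) in each annotation class (horizontal axis). Error bars are 95% exact binomial intervals for the thresholded peaks, and the promoter bar stands at 33.1% against 13.8% for random positions.

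Promoter summits were also stronger than distal ones. The median signal value was 227.2 at the 1307 promoter summits and 199.4 at the 1630 summits over 2000 bp from any start, a difference of 0.19 on the log2 scale (two-sided permutation p = 1e-05, the smallest possible). With the list divided by signal into 5 parts, the promoter share was 42.4% (95% exact interval 38.9 to 45.9) in the strongest part and 27.8% (24.7 to 31.1) in the weakest.

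Among the arms, the small chromosome 4 held fewer peaks than its share of transcript starts, with 11 peaks or 0.278% against 0.799% of start clusters (exact binomial adjusted p = 0.000294). Arm 2L held 17.7% against 19.3% (exact adjusted p = 0.0417). The X chromosome held 17.7% (700 peaks, 95% exact interval 16.5 to 18.9) against 16.4% of start clusters and did not pass (exact adjusted p = 0.0538). It passed on the dm3 list, at 17.9% (exact adjusted p = 0.0188), and in replicate 1's own list, at 17.99% (0.0231), but not in replicate 2's, at 16.5% (0.864). The dm3 list held 4452 peaks, and its expected share was that of the dm6 start clusters. Of assembled length, X makes up 17.6%, chromosome 4 makes up 1.01% and 2L makes up 17.6%, so against length 2L did not hold fewer peaks.

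Genes that pattern the embryo were bound at their promoters more often than other genes. Of 13945 protein-coding genes, 1149 or 8.24% were promoter-bound. The share was 17 of 29 for the segmentation genes (58.6%, adjusted p = 2.26e-10 by two-sided Fisher's exact test, as for every list unless another is named). It was 6 of 8 for the Hox genes (exact adjusted p = 2.31e-05) and 10 of 23 for the dorsoventral patterning genes (43.5%, adjusted p = 2.21e-05). Among segmentation genes the strongest promoter peaks were at run, a pair-rule gene, en, the segment polarity gene engrailed, ems and oc, which are head gap genes. Their signal values were 531.0, 481.5, 478.7 and 426.7. The peak at run covered X 20690481 to 20690834, 11 bp from its start, and that at en covered 2R 11528112 to 11528553. Among Hox genes, Abd-B had a promoter peak with a signal value of 615.6 and Dfd one of 612.6, against 216.5 for abd-A and 203.3 for Scr. With genes that have any pooled entry at a start as the background, segmentation genes passed (exact adjusted p = 0.00721), and Hox genes (0.0599) and dorsoventral genes (0.0960) did not. The dorsoventral list was led by sim, the midline regulator, with 868.5, and brk, with 807.5, followed by Dr with 631.7 and Doc3 with 528.5.

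Lists for signalling and hormone response were over-represented too. Notch pathway and E(spl) genes had 12 of 21 bound (57.1%, exact adjusted p = 1.53e-07), led by E(spl)malpha-BFM with a signal value of 732.8 and mib1, a ubiquitin ligase for Notch ligands, with 691.3. Ecdysone response genes had 9 of 15 bound (exact adjusted p = 3.05e-06), led by Eip75B with 637.3, while Hr38, Hr3 and Eip74EF had signal values from 200.3 to 230.0. In replicate 1's own list 33.3% of this list was bound (exact adjusted p = 0.0232), and with the 1976 strongest peaks alone it did not pass (0.0739). The Wnt, Hedgehog and Dpp list had 9 of 30 bound (exact adjusted p = 0.00112), with brk, fz, Med and shn first. Against random lists matched on transcript start clusters and gene length, an alternative chosen after seeing the data, that list did not pass (permutation adjusted p = 0.358), nor did it with the background of genes that have a pooled entry at a start (exact adjusted p = 0.453).

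Genes for regulators of transcription and chromatin formed a further group. The C2H2 zinc finger list had 17 of 35 bound (48.6%, exact adjusted p = 6.12e-09), including l(3)neo38 itself. Without it, an alternative chosen after seeing the data, 16 of 34 were bound (exact adjusted p = 3.67e-08), led by ttk with a signal value of 972.0, cbt with 462.2 and klu with 422.5. The Polycomb and trithorax groups had 11 of 28 bound (39.3%, exact adjusted p = 2.22e-05). The neighbouring and closely related genes ph-p and ph-d came first, with signal values of 1176 and 1075, ahead of Psc with 538.7 and brm, the Brahma ATPase, with 431.3. The brm peak had no match in replicate 2. Insulator and architectural proteins had 3 of 23 bound and did not pass (exact adjusted p = 0.564), with Chro at 510.4, unmatched in replicate 2, and Cp190 at 364.8.

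Of the lists for tissues, gut and endoderm markers had 10 of 18 bound (55.6%, exact adjusted p = 2.23e-06), with fkh, a forkhead gene, at 648.2 and grn, a GATA factor gene, at 440.9. This list shares members such as wg with the patterning lists. Neural precursor regulators had 8 of 27 bound (29.6%, exact adjusted p = 0.00236), with pdm2 at 410.0 and D at 365.8. Neuron markers had 7 of 28 bound (exact adjusted p = 0.0121), with elav at 380.3. They did not pass against matched lists (permutation adjusted p = 0.917), with a promoter window of 250 bp (exact adjusted p = 0.132), with the 1976 strongest peaks (0.0935) or in replicate 1's own list (0.0802). Muscle markers had 3 of 29 bound, with Mef2 at 787.7 and Tm1 at 421.6, tracheal and epidermal genes 3 of 22, germline genes 2 of 20, and haemocyte and fat body markers 2 of 22. None of these 4 lists passed, with adjusted p from 0.564 to 0.751. When genes with any pooled entry at a start served as the background, 7 lists were over-represented. The neural precursor and neuron lists did not pass there (exact adjusted p = 0.967 for both).

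Housekeeping genes divided. Cytosolic ribosomal protein genes had 22 of 86 bound (25.6%, 95% exact interval 16.8 to 36.1, adjusted p = 5.68e-06), led by RpS27 with a signal value of 523.7 and RpL41 with 367.5. This call rested on replicate 1, whose own list had 37 of 86 bound (43.0%), while replicate 2's had 11 (12.8%, exact adjusted p = 0.0957). Mitochondrial ribosomal proteins had 5 of 73 bound, oxidative phosphorylation genes 4 of 84, proteasome subunits 0 of 48, aminoacyl-tRNA synthetases 1 of 32 and spliceosomal proteins 1 of 31. The mitochondrial ribosomal genes mRpL41 (763.8) and mRpS10 (631.6) had stronger peaks than RpS27. These ranked 35th and 78th in replicate 1 and 803rd and 697th in replicate 2, while COX7C, an oxidative phosphorylation gene, ranked 1919th and 802nd. Replication and cell cycle genes had 4 of 35 bound and heat shock proteins 5 of 26, with Hsp83 at 473.6. None of these 7 lists passed (adjusted p from 0.0531 to 0.832), although heat shock proteins passed as over-represented with promoter windows of 250 bp (0.0318) and 1000 bp (0.0296). The heat shock share was 23.1% in replicate 1's own list (exact adjusted p = 0.0607) and 11.5% in replicate 2's (0.553). Proteasome subunits passed as under-represented with the window of 1000 bp (exact adjusted p = 0.0153) and in replicate 1's own list (0.0232).

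Of the remaining lists, 6 were under-represented among promoter-bound genes. Chemoreceptors and odorant binding proteins had 2 of 258 bound (0.775%, exact adjusted p = 1.04e-06), namely Ir60e and Obp46a. Chitin and cuticle proteins had 0 of 122 (95% exact interval 0 to 2.98%, adjusted p = 0.000113) and seminal fluid and testis proteins 0 of 76 (0 to 4.74%, adjusted p = 0.00522). Replication-dependent histones had 0 of 111 (exact adjusted p = 0.000384), but these repeated genes share sequence, and how reads with several matches were treated is not given in the sources used here. Among small RNA genes, 3 of 269 snoRNA genes (exact adjusted p = 9.07e-06) and 5 of 290 tRNA genes (adjusted p = 4.48e-05) were bound. Detoxification genes had 6 of 152, immune genes 0 of 48, snRNA genes 1 of 32 and lncRNA genes 222 of 3261, and these did not pass (exact adjusted p from 0.0531 to 0.600). In replicate 1's own list 10 lists were under-represented, among them detoxification (exact adjusted p = 0.0454), immune (0.0232) and lncRNA genes (2.05e-06). Detoxification genes also passed with the window of 1000 bp (exact adjusted p = 0.0153). The lncRNA genes also passed as under-represented with the window of 250 bp (exact adjusted p = 0.00026) and with nearest starts only (0.000506), and with the window of 1000 bp their direction turned (0.541). In replicate 1's own list 2.60% of snoRNA and 2.76% of tRNA genes were bound, and in replicate 2's own list 0.388% of chemoreceptors, all still under-represented. Against matched random lists, cuticle proteins (permutation adjusted p = 0.0262) and chemoreceptors (0.00375) stayed under-represented, and histones (0.264) and seminal fluid proteins (0.280) did not. Seminal fluid proteins also did not pass with the 1976 strongest peaks alone (exact adjusted p = 0.103). With genes that have a pooled entry at a start as the background, tRNA genes (exact adjusted p = 0.00169) stayed so and lncRNA genes (0.0072) became so, while chemoreceptors (0.0915), snoRNA genes (0.179), cuticle proteins (0.776) and seminal fluid proteins (0.776) did not.

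**Figure D3:**
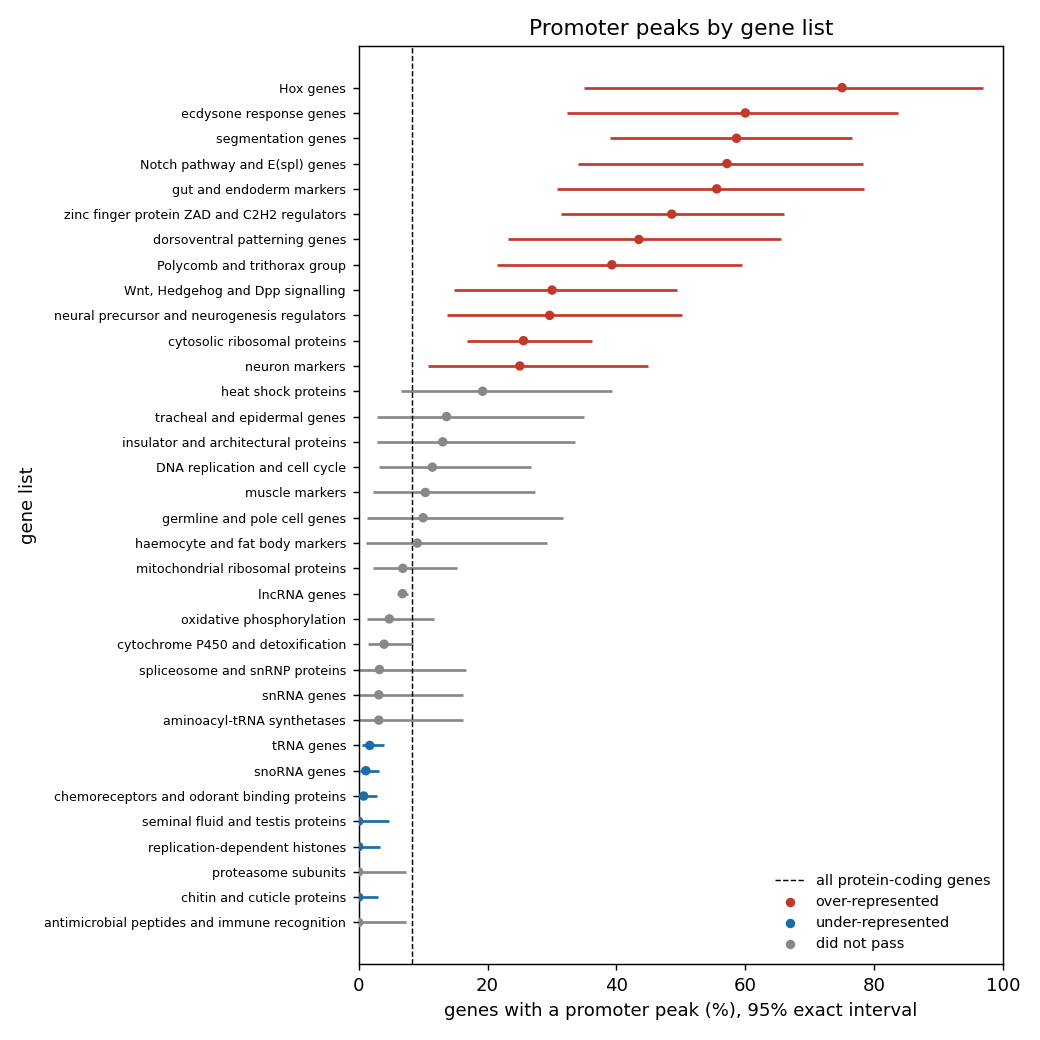
Share of genes with a promoter peak (horizontal axis, %) in each of the 34 gene lists (vertical axis), with 95% exact binomial intervals. Colours mark the 12 over-represented, 6 under-represented and 16 remaining lists, and the dashed line is the 8.24% of all protein-coding genes.

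The sequence at the summits was rich in runs of C, or of G on the other strand. The leading 8-mer was CCCACCCC (reverse complement GGGGTGGG), present in 6.37% of the 3953 summit windows and 0.506% of flanking windows (exact McNemar adjusted p = 2.77e-50). It was also the leading 8-mer when alternate peaks were searched, at 6.17% and 6.58% of the peaks not used to find it. Of 1378 8-mers tested, 448 were enriched and 435 depleted at summits, and 19 of the 20 with the smallest p had at least 6 C. Shares were similar with the A near the middle: CCCCACCC was at 6.55%, CCCCCACC at 6.05% and CCACCCCC at 6.20%. These 8-mers overlap, so 1 longer C-rich stretch can hold several of them, as at mirr, where the window held 3. The shares therefore do not show whether the position of the A matters. With the A at either end, ACCCCCCC stood at 1.92% and CCCCCCCA at 1.82%, and CCCCCCCC at 2.83%. Any of the 8 arrangements of 7 C and 1 A, a family chosen after the leading 8-mer was seen, occurred in 672 of 3953 summit windows (95% exact interval 15.8% to 18.2%) and 2.28% of flanks. At the erm peak, GGGGGTGG lay at 2L 1970656 to 1970663, and at brk GGGGTGGG lay at X 7306739 to 7306746. The window at mirr, 3L 12693085 to 12693185, read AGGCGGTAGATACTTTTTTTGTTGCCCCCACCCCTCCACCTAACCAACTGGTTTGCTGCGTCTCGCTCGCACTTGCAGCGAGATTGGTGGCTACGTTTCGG. Not every strong peak held 1 of these 8 arrangements: 6 of the 20 strongest did, and the window of the strongest peak did not. Other C-rich 8-mers outside the family were also enriched, such as CCCCCTCC (5.79% of summit windows, 0.810% of flanks) and CCCCGCCC (4.35%, 0.405%). The kay window held none of the 8 but did hold CCTCCCCC, so this count does not cover all C-rich sequence.

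Of the 32 preset motifs, 5 were enriched at summits. The GAGA element GAGAGAG, the site of the factor encoded by Trl, was in 8.32% of summit windows against 3.39% of flanks (exact McNemar adjusted p = 5.91e-20). It showed no sharp maximum at the summit. In 20 bp bins centred 10 and 130 bp away its share was 2.15% and 2.20% on one side, and 2.28% and 1.85% on the other. The CA repeat CACACACA was in 7.34% against 4.73% (exact adjusted p = 9.06e-06), the Mad/Brk GC site in 12.1% against 9.06%, the CTCF site in 0.784% against 0.202% and the Sp/KLF box in 1.37% against 0.582%. With weaker pooled entries as the control, 2 motifs passed as enriched, both among these 5, the GAGA element and the CA repeat. The Mad/Brk site (12.9%) and the Sp/KLF box (1.42%) were then no rarer in the control, against shuffled windows the Mad/Brk site passed as depleted (13.9% in the control, exact adjusted p = 0.0391), and the CTCF site also did not pass in replicate 2's own list (exact adjusted p = 0.394) or with the 1976 strongest peaks alone (0.126). Depleted motifs were the homeodomain core TAATTA (3.47% against 6.27%, exact adjusted p = 5.21e-08), the A tract, the Stat92E site, the E-box CATATG and the initiator. With weaker pooled entries as the control, the Stat92E site (2.05%, exact adjusted p = 0.835) and CATATG (2.56%, p = 1) did not pass. With the 1976 strongest peaks alone, the Stat92E site (exact adjusted p = 0.259), CATATG (0.107) and the initiator (0.238) did not pass. Against shuffled windows none of these 5 passed as depleted, and CATATG did not pass in replicate 1's own list (exact adjusted p = 0.0688) or the initiator in replicate 2's (0.824). The Zelda site, at 0.557% against 0.531%, did not pass. Summit windows held 49.1% GC against 41.3% in flanks, a mean difference of 7.88 ± 0.235 percentage points (SE over peaks, sign-flip permutation p = 1e-05, the smallest possible). The difference was 4.43 ± 0.436 points at promoter summits and 9.59 ± 0.271 at the others, and weaker pooled entries held 46.8% GC.

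**Figure D4:**
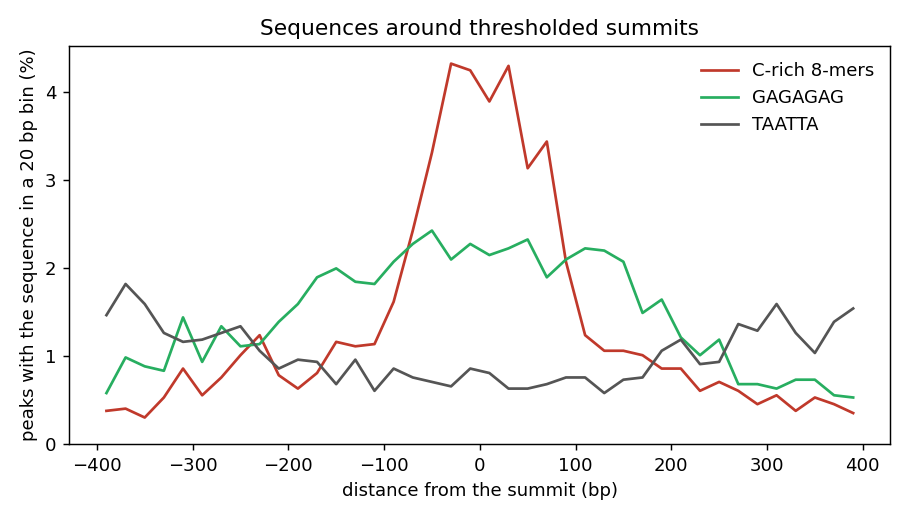
Share of the 3953 thresholded peaks with a sequence (vertical axis, %) in each 20 bp bin by distance from the summit (horizontal axis, bp), for the 8 C-rich 8-mers, GAGAGAG and TAATTA. The C-rich line is highest within 50 bp of the summit, near 4.33%, and falls to 0.354% at 390 bp.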

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

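The C-rich family, the matched random lists and the test on housekeeping genes were chosen after the results were seen.

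On the older build dm3, a few entries lay on unplaced or heterochromatic sequence, which the comparisons above do not use. The list from pooled replicates held 6 such entries and the list of replicate 2 held 7, above the 3 that a count of 0 allows. The list of replicate 1 held 3. The best of them ranked 9345th in replicate 2 and 14447th in the pooled list, and 0 were among the thresholded peaks.

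Of the 34 lists, 12 were over-represented at promoter peaks, among them 1 of ribosomal protein genes, and 7 were with genes that have a pooled entry at a start as the background. More transcript starts and longer genes were argued against as the whole cause, since 10 of the 12 lists stayed over-represented against random lists matched on both. The Wnt, Hedgehog and Dpp list and the neuron markers did not, so gene structure may account for those. In the thresholded list, binding shared by housekeeping genes at large was argued against for the ribosomal protein genes, by counts already seen: 4.39% (95% exact interval 2.03 to 8.17) of mitochondrial ribosomal, proteasome and oxidative phosphorylation genes were bound, against 25.6% (16.8 to 36.1). This concerns the share of genes bound and not peak strength, since mRpL41 and mRpS10 had stronger peaks than RpS27. In replicate 2's own list the ribosomal share was 12.8% (6.56 to 21.7), which overlaps that interval, and since transcription was not measured here, an effect of its level stays open and no biological explanation was tested.

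The C-rich sequence might follow from base composition, since summits were richer in GC. Weaker pooled entries matched on GC content held the C-rich 8-mers in 8.73% of windows, 51.3% of the share in thresholded peaks (95% interval 45.3 to 57.9). Dinucleotide-shuffled summit windows held them at 46.0% of the real share (40.4 to 52.1). The shuffled value met the bound written beforehand, below 50% with an exact McNemar p under the threshold (p = 8.94e-43), but that its interval must clear the bound too was required only after the value was seen. The C-rich 8-mers were in 7.82% of shuffled windows, and the 95% exact interval for matched entries was 7.87% to 9.65%. Both lay below the interval of 15.8% to 18.2% for the real summit windows. These values argue against GC content or dinucleotide composition as the whole cause of the pattern. Neither control was matched on long runs of C, so the values do not tell these 8-mers from other C-rich sequence. Both controls also lay above the 2.28% of flanks, so composition may be a part of it. As both ratio intervals span 50%, the size of that part cannot be told, and weaker entries could themselves hold bound sites.

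The peaks at l(3)neo38 may reflect extra copies of the locus carried by the transgene. Weak entries around the gene, 8 in 18091 bp, stood at percentile 59.5 of windows around 200 other strong peaks, within the bound set beforehand against this explanation. That bound was judged wrong in design after the value was seen, because entries over the threshold are taken out of the weak ones, and the 12 summits over it stood at percentile 97.8. Extra copies and binding of the gene's own product therefore cannot be told apart with these lists.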

How the results depend on the processing

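No paired analysis was possible because there is only 1 group. Of 62 alternative values of the main results, 51 kept their direction and side of the threshold or their size. The stricter threshold by construction keeps 1976 peaks. The share of peaks in both replicates was 49.0% with summits within 50 bp, 70.3% within 250 bp, 70.9% by 1 bp overlap and 86.2% with longer replicate lists. It was 64.4% when the thresholded list and both replicate lists were each cut to their 1976 strongest entries. The cause of these differences was not tested. The X chromosome share passed the test on the dm3 list at 17.9%, against the start clusters of dm6. It ranged from 16.5% to 17.99% over the 2 lists that leave out a replicate. The cause of these changes was not tested. Over-represented lists fell from 12 to 7 with genes that have a pooled entry at a start as the background, where 3496 genes were tested in place of 13945. Chosen after seeing the data, matched random lists gave 10 and leaving l(3)neo38 out of its list gave 12. Enriched motifs numbered 2 against weaker pooled entries and 9 against shuffled windows, in place of 5. The direction turned against shuffled windows for the initiator (7.59% of summit windows), the E-box CATATG (2.53%), the homeodomain core (3.47%), the A tract (3.34%) and the Mad/Brk site (12.1%), which then passed as depleted. It turned against weaker entries for the Sp/KLF box (1.37%) and the Mad/Brk site (12.1%); the cause was not tested. Of 395 values for the 18 lists and 10 motifs that passed and for single peaks and genes, 358 kept their call, 26 were weaker, 4 moved and 7 turned. For the lists 111 of 126 values kept their call and 15 were weaker. For the motifs only 42 of 60 did, with 11 weaker and 7 turned. The rest were single peaks and genes, which could keep their call though the rank changed, as at RpS27 (262nd, and 969th in replicate 2's own list). Of the 16 lists that did not pass, 5 passed under another setting (11 of 112 values). Of the 22 such motifs, 9 did (of 132 values, 11 in the same direction and 3 in the other), among them the Pho core, which was enriched in replicate 2's own list (20.3%, exact adjusted p = 0.000421) and depleted against weaker entries (18.8% against 22.2%, 0.00108). Depth is unknown, so its effect on the number of peaks could not be measured.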

Other observations

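All tests in this part were chosen after the results were seen. The lists of the replicates held different numbers of ribosomal protein promoters. Among the 3953 strongest entries of each replicate, 37 of 86 ribosomal protein genes were bound in replicate 1 (43.0%, 95% exact interval 32.4 to 54.2) and 11 in replicate 2 (12.8%, 6.56 to 21.7). Replicate 1's list alone held 28 of them and replicate 2's alone held 2. At the 18 ribosomal protein summits matched in both lists the median rank was 1784 in replicate 1 and 3990.5 in replicate 2. At 1142 other promoter summits these were 1564.5 and 1839, and at 1518 distal summits 2409.5 and 2106. These are given as values, since each replicate is 1 library and a test across genes would restate the counts that drew attention to the list. None of the 23 ribosomal protein summits held a C-rich 8-mer or GAGAGAG, against 14.6% and 11.4% of 1284 other promoter summits, but these differences did not pass (Fisher's exact p = 0.0634 and 0.0993).

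Counting summits in gene bodies and 2000 bp around them, against 10000 random lists matched on gene length, 9 of 30 coding lists had more summits and 4 had fewer (Benjamini-Hochberg adjusted p under the threshold). Polycomb and trithorax group genes had 3.11 summits per gene against 0.616 in matched lists (permutation adjusted p = 0.0015, from the smallest p these draws can give), and the 21 Notch pathway genes had 2.52 against 0.684 (adjusted p = 0.00667). Each of the 8 Hox genes had a summit, with 4.38 per gene against 1.67, which did not pass (permutation adjusted p = 0.108). Cytochrome P450 and detoxification genes had 0.0592 against 0.177 (permutation adjusted p = 0.006), although their promoter share did not pass.

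The C-rich 8-mers and the GAGA element differed by location, and both were more frequent in the strongest peaks than in the weakest. C-rich 8-mers were in 14.3% of promoter summit windows and 18.3% of the others (odds ratio 0.744, Fisher's exact p = 0.00161), while GAGAGAG was in 11.2% and 6.92% (odds ratio 1.69, p = 9.57e-06). The flanks differed in the same directions, with C-rich 8-mers in 1.84% at promoter peaks and 2.49% at the others. For GAGAGAG the flanks held 3.90% and 3.14%. Whether enrichment over the flanks differs by location was not tested. C-rich 8-mers and GAGAGAG occurred together in 52 windows, with no detectable association (odds ratio 0.91, Fisher's exact p = 0.592). In the strongest of 5 parts of the list 22.5% of windows held a C-rich 8-mer (95% exact interval 19.6 to 25.6), and in the weakest 13.7% (11.3 to 16.2). The flanks of the same peaks held one in 2.78% and 0.885%, so the ratio to the flanks was not higher in the strongest. For GAGAGAG these shares were 11.8% (9.60 to 14.2) and 6.45% (4.84 to 8.39). Thresholded summits also lay close together, with 1039 neighbouring pairs within 2000 bp against 482 on average, and at most 523, in 100 draws of as many weaker entries. Some of these pairs are summits of 1 wide interval, as at l(3)neo38, and summits within 250 bp merged to 3641 clusters. The weaker entries were also kept only where they overlapped no thresholded peak. How much of the excess this makes up was not tested.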
